A study of Mus musculus with 25 samples.

How the data were processed

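The series holds 25 sequencing libraries from mK4, a mouse cell line derived from embryonic kidney mesenchyme. The strain label of 1 N1/N1 library and that of the Mef2c/MAML library differ from the rest (CD2 and CD3 against CD1); the strain label was not used here, and a difference in source is not excluded. In split DamID (SpDamID), an inactive part of the bacterial adenine methylase Dam is fused to each of 2 proteins, and the enzyme marks GATC sites where both proteins meet. Per the labels' protocols, methylated DNA was cut with DpnI, amplified by ligation-mediated PCR, sonicated and sequenced. FAIRE recovers open chromatin from formaldehyde cross-linked nuclei by phenol-chloroform extraction, and it was set against input DNA. ChIP used a myc epitope tag on N1. Libraries were grouped by their labels, and SpDamID libraries number 3 each for the Dam control, N1/RBP, N1/MAML and N1/p300, 2 for N1/N1, and 1 each for Mef2c/MAML and Mef2c/p300. FAIRE has 3 control libraries, 3 N1wt libraries and 1 N1wt input, and ChIP has 1 N1 library and 1 input.

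The values used are 9 lists of regions for the whole series, with no value per library. For each of the 6 SpDamID lists the authors deposited a whole-number score per region for the complex over Dam at a confidence level of at least 0.999, per the file headers. Each of these lists was matched to its complex by the initials of the 2 proteins, since no label spells its short name out, and the FAIRE lists were matched to N1wt in the same way. The scale of the score is not given in the sources used here. The track names of N1/RBP, N1/MAML and N1/p300 carry the word median, per the file headers. The 2 FAIRE lists hold peaks that MACS called in Galaxy, per the file headers, with the deposited MACS score, which is 50.01 or more in the total list and 50.16 or more in the Notch-dependent list. How Notch-dependent peaks were chosen is not given in the sources used here. For each ChIP region the deposited table gives a signal for the ChIP and a signal for the input, with a ratio of the ChIP to the input that is 10.0097 or more throughout. That ratio equals the quotient of both signals within a relative error of 4.79e-10. The ChIP columns carry no header, so which is ChIP and which is input was read from this quotient. The input signal is exactly 0.1 in 20103 of the 22307 ChIP regions. Coordinates are of build mm9, per the submitters' processing notes. Aligner and caller versions are not given in the sources used here.

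Regions were compared as 1-based positions with both ends included, after adding 1 base to the FAIRE starts. The 19 autosomes and the X and Y chromosomes were used, which left out 43 total and 7 Notch-dependent FAIRE regions on other contigs. Regions counted as shared with an overlap of 1 bp or more. The observed share was set against 1000 rotations of the overlapped list by a random offset around each chromosome, which keep number, length and spacing. The two-sided p is 2 times the smaller tail, and 0.002 is the smallest that 1000 rotations give. Differences between shares carry a standard error (SE) from a delete-a-block jackknife over 5 Mb blocks, a 95% normal interval and a two-sided p. All p-values were adjusted by Benjamini-Hochberg within each family of tests. Pairs of lists with a common protein were compared with the rest by an exact permutation over all 720 relabellings of the 6 lists. Other FAIRE regions are the 17083 total regions that overlap no Notch-dependent region.

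Regions differ in length between the SpDamID lists, so each overlap was repeated, as an alternative added after the lists were seen, with SpDamID regions of 405 to 786 bp. This range runs from the highest 5th to the lowest 95th percentile of length over the 6 lists. Also added were other FAIRE regions weighted to the score and length of the Notch-dependent ones, once with the score each region has in its own list and once with the total list's score for the 2270 Notch-dependent regions found there, ChIP regions of at least 300 bp, ChIP regions with an input off the fixed value, and regions found in only 1 of the lists compared. Alternatives fixed before the data were examined were overlap of 50% or more of the smaller region, the region centre, uniform random placement, the upper part of each list from its median score, regions within 500 bp merged, autosomes only, 20 Mb blocks and the Jaccard index.

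The overlap functions gave 0 differences from a plain loop over 900 tested cases. In simulated lists with regions planted on N1/RBP, planted shares of 10 and 40% came back as 9.89 and 40.0%. The rotation test called 6% of 100 randomly rotated FAIRE lists at 0.05. The jackknife called 5.5% of 400 random classes of FAIRE regions with no difference in N1/RBP overlap, and 99.5% of 400 with a planted difference of 5 points. Its 95% intervals held the planted 5 points in 94.2% of draws. The random classes were drawn region by region, without clustering, and the random lists were themselves made by rotation. These checks therefore do not show that the errors hold for classes of regions that cluster.

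Regions were named by a rule fixed before the data were examined, and the fallback of that rule for a series without gene positions was used. It takes the 5 highest scoring regions of each SpDamID list, the 10 regions with the best mean score rank among N1/RBP regions in all 4 N1 lists, and up to 10 Notch-dependent FAIRE regions in the most lists, with ties broken by N1/RBP score. Where nearby regions were singled out beyond that rule, the text says so. Gene features, gene lists and motifs need mm9 genes or sequence and were not analysed here. With no value per library, depth per library is unknown, replicates were not compared, and every error describes variation along the genome. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.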

Results

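Sites marked by 6 pairs of proteins were mapped by SpDamID in mK4 cells. Among them, 4 pairs hold N1 (Notch1), whose cleaved form enters the nucleus and acts on transcription. Its partners were RBP, the DNA-binding protein of the Notch complex, and MAML, the co-activator that joins N1 and RBP. Further partners were p300, an acetyltransferase that MAML recruits, and N1 itself, used to read out dimers. Whether N1/N1 signal needs a dimer was not tested here. The other pairs join Mef2c, a MADS-box transcription factor, to MAML or to p300. Open chromatin was mapped by FAIRE in N1wt and control cells, and N1 by ChIP. The deposited lists held 28281 regions for N1/RBP, 16547 for N1/MAML, 22360 for N1/p300, 31938 for N1/N1, 50381 for Mef2c/MAML and 28757 for Mef2c/p300. FAIRE gave 19396 total and 2403 Notch-dependent regions, and ChIP gave 22307 regions. Median region lengths were 667, 517, 566, 754, 486 and 630 bp for the SpDamID lists in that order, 903 bp for total FAIRE, 816 bp for Notch-dependent FAIRE and 137 bp for ChIP. The N1/RBP regions covered 20.6 Mb and the Mef2c/MAML regions 25.8 Mb. The N1/N1 list covered 31.4 Mb, of which a single region from the first base of chromosome 11 to base 3002119 took 3002119 bp. Each list pools its libraries, so no value has a replicate error and the depth per library is unknown. Every SE below comes from blocks of the genome.

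The first comparison asked how far the complexes share sites. All 6 complexes shared sites with one another far above chance placement. The largest fold over rotated lists was that of N1/MAML regions in N1/p300, 52.2% ± 0.555 (SE) and 38.8-fold, and 57.1% ± 0.525 of the 22360 N1/p300 regions lay on an N1/RBP region, 37.9-fold. N1/N1 and N1/RBP shared 52.1% ± 0.431 of the N1/N1 regions and 58.8% ± 0.456 of the N1/RBP regions. Mef2c/MAML, which holds no Notch protein, still lay on 54.5% ± 0.431 of the N1/RBP regions and 63.4% ± 0.938 of the N1/MAML regions. The smallest fold was that of Mef2c/p300 regions in N1/MAML, 13.6% ± 0.332 and 12.8-fold. All 30 directed overlaps had an adjusted p of 0.002, the smallest the rotations give. The 9 pairs of lists with a common protein had a geometric mean of 26.8-fold, against 18.1-fold for the 6 pairs with none (exact permutation over 720 relabellings, two-sided p = 0.0167). By the Jaccard index of covered bases the means were 0.191 and 0.149 and the difference did not pass (exact permutation p = 0.233). Every pair with no common protein joins an N1 list to a Mef2c list. Each Mef2c list comes from 1 library and each N1 list from 2 or 3. A common protein therefore cannot be separated from these differences between N1 and Mef2c lists. All lists were scored against the same Dam control libraries and lie on a common map of fragments, with 0 partial overlaps among 96409 distinct fragments. Part of every overlap between SpDamID lists may come from that control and that map, and the lists do not allow the control to be split.

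**Figure D1:**
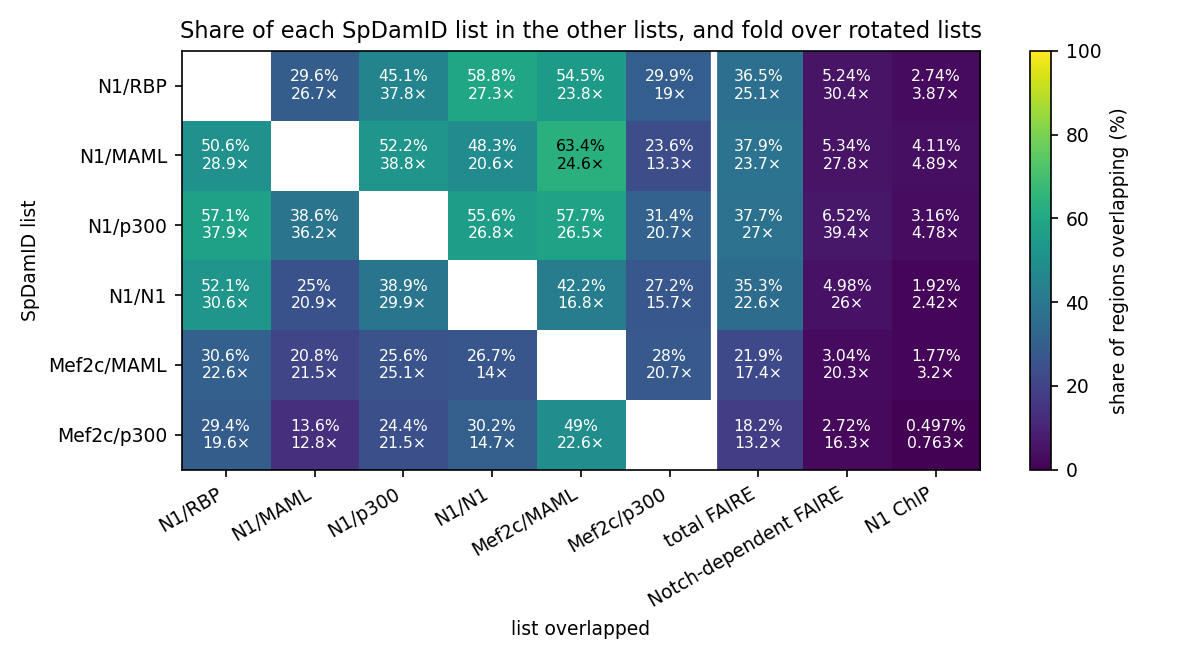
Share of the regions of each SpDamID list (rows) that overlap each other SpDamID list, FAIRE and N1 ChIP (columns), in percent by colour and number, with the fold over 1000 rotated lists beneath. N1/RBP and N1/p300 regions have 37.8- and 37.9-fold overlaps with each other, and N1/MAML regions lie in N1 ChIP 4.89-fold as often as in rotated lists.

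Sites common to the Notch complexes were read from the N1/RBP regions found in all 3 other N1 lists. There were 5730 such regions, 20.3% of the N1/RBP list, against a mean of 102 in rotated lists (permutation by rotation, p = 0.002). Of the common N1 regions, 60.2% lay in open chromatin by total FAIRE, 9.25% in Notch-dependent FAIRE and 5.29% in N1 ChIP. These sites were not private to Notch: 5410 of them (94.4%) also lay in a Mef2c list, 92.8% in Mef2c/MAML and 52.3% in Mef2c/p300. Restricting each list to scores from its median up left 2668 regions.

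Open chromatin tracked the number of N1 lists that held a fragment. Total FAIRE held 6.79% ± 0.184 of the 39987 fragments in Mef2c lists only, 17.2% ± 0.353 of the 32096 in 1 N1 list and 60.2% ± 0.973 of the 5730 in all 4. Notch-dependent FAIRE held 0.9% ± 0.0544, 2.51% ± 0.115 and 9.25% ± 0.491 of the same classes, and N1 ChIP held 0.435% ± 0.0446, 1.3% ± 0.102 and 5.29% ± 0.482. Fragments in all 4 N1 lists exceeded those in 1 by 42.9 points for total FAIRE, 6.74 points for Notch-dependent FAIRE and 3.99 points for ChIP, with adjusted p-values of 1.09e-45 and 6.07e-20 for the last 2 and a smaller value for the first. These classes were formed after the lists were seen. Among fragments of 405 to 786 bp the differences were 42.8, 6.15 and 3.43 points.

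**Figure D2:**
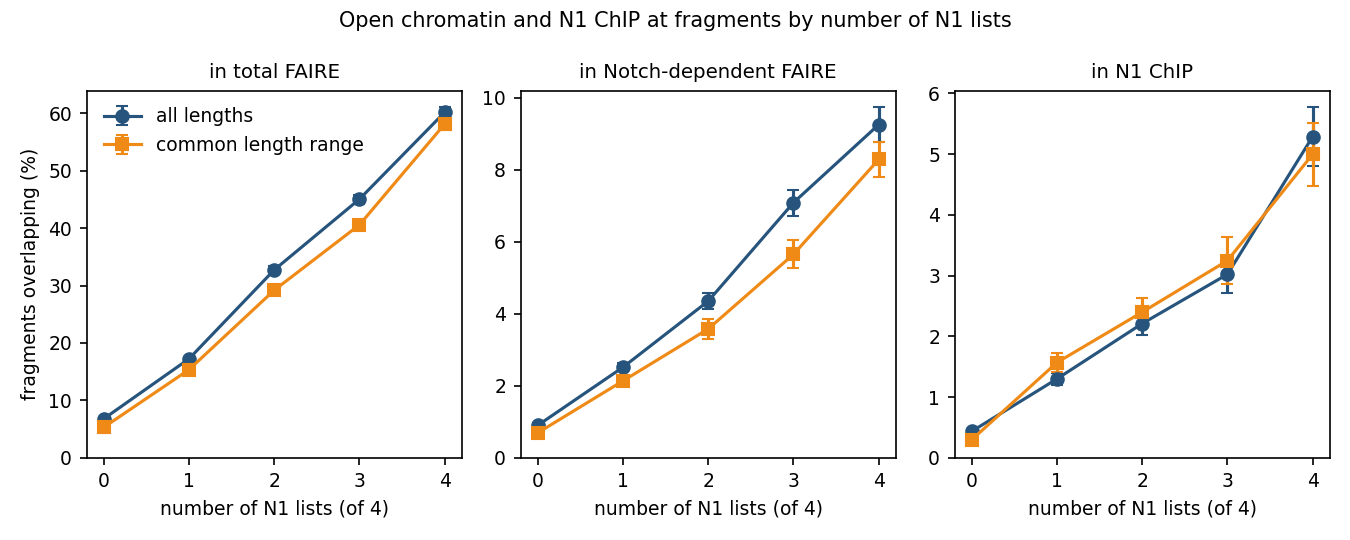
Share of SpDamID fragments that overlap total FAIRE, Notch-dependent FAIRE and N1 ChIP (percent, 3 panels) by the number of N1 lists holding the fragment, for all lengths and for 405 to 786 bp; bars are block jackknife SEs, and fragments in 0 N1 lists are in Mef2c lists only. The share in total FAIRE goes from 6.79% at 0 lists to 60.2% at 4.

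The common N1 regions with the best mean score rank lay at few places. The leading 4 fell close together on chromosome 2 (mm9), at 26318173 to 26319926, 26315080 to 26316404, 26320207 to 26320456 and 26316842 to 26317945, with N1/RBP scores of 824, 833, 795 and 705 and N1/N1 scores of 847, 838, 832 and 761. All 4 lay in Notch-dependent FAIRE, the last 3 of them lay in N1 ChIP, and the first was the only one of them in a Mef2c list, at a Mef2c/MAML score of 167. These 4 lie in a stretch, 26315080 to 26359136, that holds 4 to 7 of the 50 highest scoring regions of each N1 list and 0 of those of either Mef2c list, and the closing section weighs what such stretches come from. One source weighed there, DNA that carries the N1 sequence itself, could also give FAIRE and ChIP signal. On chromosome 15, 13139868 to 13140308 and the adjacent 13140309 to 13140643 scored 733 and 703 for N1/RBP and 761 and 706 for N1/N1. Both lay in Mef2c/MAML and in the same Notch-dependent FAIRE region, 13129703 to 13153225. That region is far longer than the 95th percentile of its list, 1741.7 bp. Its MACS score of 67.19 lies below the list's median of 132.08, so this overlap says little about the 2 fragments. On chromosome 18, 20711755 to 20712600 scored 718 for N1/RBP and 748 for N1/N1 and also lay in Notch-dependent FAIRE. The remaining 3, on chromosome 7 at 127895332 to 127895801, chromosome 3 at 137215733 to 137216281 and chromosome 11 at 62363579 to 62364003, lay in total but not in Notch-dependent FAIRE and in both Mef2c lists.

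SpDamID sites were next set against FAIRE and ChIP, the comparison that the series design names. A larger share of Notch than of Mef2c regions lay in the open chromatin of N1wt cells. Both FAIRE lists are from N1wt cells, and no FAIRE library is labelled with a Mef2c fusion. Open chromatin in cells with the Mef2c fusions is therefore unknown. Total FAIRE held 36.5% ± 0.583 of N1/RBP, 37.9% ± 0.815 of N1/MAML, 37.7% ± 0.679 of N1/p300 and 35.3% ± 0.594 of N1/N1 regions, but 21.9% ± 0.455 of Mef2c/MAML and 18.2% ± 0.449 of Mef2c/p300 regions. Notch-dependent FAIRE held 6.52% ± 0.26 of N1/p300 regions, 39.4-fold over rotation, 5.34% ± 0.248 of N1/MAML, 5.24% ± 0.208 of N1/RBP and 4.98% ± 0.186 of N1/N1 regions. N1 ChIP held few: 4.11% ± 0.288 of N1/MAML regions (4.89-fold), 3.16% ± 0.242 of N1/p300, 2.74% ± 0.206 of N1/RBP and 1.92% ± 0.159 of N1/N1 regions (2.42-fold). All of these exceeded rotation at an adjusted p of 0.00212. So did Mef2c/MAML regions, of which N1 ChIP held 1.77% ± 0.13 (3.2-fold), a larger fold than that of N1/N1. With ChIP regions of at least 300 bp the folds were larger, 10.3 for N1/MAML and for N1/p300, 8.60 for N1/RBP and 5.41 for N1/N1 (permutation by rotation, adjusted p = 0.002). For Mef2c/p300 regions the share in N1 ChIP was 0.497% ± 0.0667, 0.763-fold over rotation in all ChIP regions (permutation by rotation, adjusted p = 0.018) but 1.69-fold in those of at least 300 bp (adjusted p = 0.002). ChIP regions met SpDamID regions only with identical ends, and short ones almost never did. Rotation breaks this common map and lets short regions overlap in part, so folds for ChIP depend on the map, and the value below 1 is not evidence of avoidance.

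Regions with higher scores lay in open chromatin more often in every SpDamID list. The upper score quartile of N1/N1 had 54.0% ± 0.939 of its regions in total FAIRE, against 23.0% ± 0.569 in the lower quartile. For N1/p300 the upper and lower quartiles had 11.5% ± 0.567 and 3.67% ± 0.267 in Notch-dependent FAIRE. The smallest difference for total FAIRE was in Mef2c/p300, 22.8% ± 0.781 against 15.2% ± 0.521 (jackknife over n = 519 blocks, adjusted p = 6.52e-23). For ChIP, upper quartiles were higher in 5 of the 6 lists; Mef2c/p300 gave 0.403% and 0.57% (n = 519 blocks, adjusted p = 0.119).

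The same co-activator was then compared between N1 and Mef2c. With MAML, N1 regions exceeded Mef2c regions by 16.0 ± 0.543 points in total FAIRE, 2.31 ± 0.182 points in Notch-dependent FAIRE and 2.34 ± 0.184 points in N1 ChIP. With p300, the differences were 19.6 ± 0.444, 3.79 ± 0.193 and 2.66 ± 0.204 points. On the log2 scale the ChIP share of N1/p300 was 2.67 ± 0.15 above that of Mef2c/p300, and that of N1/MAML was 1.22 ± 0.05 above that of Mef2c/MAML. All 6 differences passed, the least significant at an adjusted p of 8.12e-37, and all 42 alternative values kept the direction and the call, 32 of them with a changed difference. Each Mef2c list comes from 1 library and each N1 list from 3, so a difference between libraries cannot be separated from that between complexes. Nor can the FAIRE differences be separated from the use of N1wt cells for both FAIRE lists. The Mef2c lists are also longer, 50381 against 16547 regions with MAML and 28757 against 22360 with p300. No alternative matched the number of regions, and shares in total FAIRE were lower at lower scores, so list size is not separated either. Counted by total FAIRE region, N1/MAML marked 25.9% and Mef2c/MAML 40.8%, the reverse order. With p300 the order stayed, 33.2% for N1/p300 and 22.1% for Mef2c/p300.

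N1/N1 was compared with the other N1 complexes because the series concerns enhancers that respond to Notch dimers. N1/N1 shares lay below those of the other N1 lists, by amounts that changed with the setting. In total FAIRE, the N1/N1 share minus that of the other list was -1.17 ± 0.304 points for N1/RBP, -2.6 ± 0.518 for N1/MAML and -2.39 ± 0.338 for N1/p300. In Notch-dependent FAIRE it was -1.54 ± 0.133 points for N1/p300, -0.367 ± 0.176 for N1/MAML and -0.269 ± 0.102 for N1/RBP. In N1 ChIP it was -0.821 ± 0.0973 points for N1/RBP, -2.19 ± 0.174 for N1/MAML and -1.24 ± 0.123 for N1/p300. All 9 differences passed, with adjusted p-values up to 0.0365. The N1/N1 list comes from 2 libraries, 1 with a differing strain label, and each other N1 list from 3. Track names of the other N1 lists also carry the word median. A difference between libraries or in processing cannot be separated from that between complexes. Against N1/RBP and N1/p300 the direction in total FAIRE depended on fragment length: among regions of 405 to 786 bp, N1/N1 was 2.94 and 2.85 points above them, with adjusted p-values of 1.35e-14 and 1.32e-12. Against N1/MAML the difference was larger in that range, -5.72 points, and so it was by 50% overlap (-6.07) and by region centre (-6.9). Direction also depended on the regions the lists share: with regions found in only 1 of the lists compared, N1/N1 was 6.86 points above N1/MAML and 4.53 above N1/p300 in total FAIRE, and 1.02 above N1/MAML in Notch-dependent FAIRE (jackknife over n = 529 and 537 blocks, largest adjusted p = 6.2e-05).

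Notch-dependent FAIRE regions were compared with the other open regions, to ask which complexes mark sites whose accessibility depends on Notch. N1/p300 marked 44.2% ± 1.13 of the 2396 Notch-dependent regions and 31.6% ± 0.477 of the 17083 others, a difference of 12.6 ± 1.23 points (jackknife over n = 523 blocks, adjusted p = 2.32e-24). N1/N1 marked 48.9% ± 1.05 and 42.3% ± 0.564, and N1/RBP marked 46.5% ± 1.06 and 40.1% ± 0.524. The Mef2c/p300 shares were 26.3% ± 0.976 and 21.4% ± 0.509. N1/MAML and Mef2c/MAML differed least, by 3.31 ± 1.12 and 3.08 ± 1.18 points (n = 523 blocks, adjusted p = 0.00367 and 0.00905). Of the Notch-dependent regions, N1/MAML marked 28.8% ± 1.02 and Mef2c/MAML, which holds no Notch protein, marked more, 43.4% ± 1.11. The difference for N1/p300 exceeded that for Mef2c/p300 by 7.73 ± 1.14 points (n = 523 blocks, adjusted p = 3.04e-11) and that for N1/MAML by 9.33 ± 1.13 points (adjusted p = 5.25e-16). Between N1/MAML and Mef2c/MAML the differences were 0.23 points apart, with a 95% interval from -1.78 to 2.24. No alternative for this pair passed on both scales: by region centre it was -2.68 points (n = 523 blocks, adjusted p = 0.00519) and -0.034 on the log2 scale (adjusted p = 0.64), in the upper part by score 0.113 points (adjusted p = 0.901) and 0.123 (adjusted p = 0.0451), with other regions weighted to length and to the score in each list 0.127 points (adjusted p = 0.903) and 0.141 (adjusted p = 0.00463), and weighted to length and the total FAIRE score -0.208 points (adjusted p = 0.843) and 0.12 (adjusted p = 0.0165). Weighted the last way, the differences for the 6 lists were larger, from 6.45 to 16.2 points. Among SpDamID regions of 405 to 786 bp, the differences for N1/RBP, N1/MAML, N1/N1 and Mef2c/MAML were 1.29 to 1.95 points and no longer passed, and those for N1/p300 and Mef2c/p300 fell to 7.11 and 2.36 points, which passed (n = 523 blocks, adjusted p = 2.95e-09 and 0.0196).

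N1 ChIP went the other way. ChIP regions lay in 3.21% ± 0.412 of Notch-dependent regions and 20.6% ± 0.614 of other FAIRE regions, a log2 ratio of -2.68 ± 0.18 (n = 523 blocks, adjusted p = 1.65e-159). Total FAIRE regions as a whole overlapped ChIP 20.5-fold over rotation, and the Notch-dependent ones 3.79-fold. For the 2270 Notch-dependent regions that are also in the total list, the order was the same within each quartile of the total FAIRE score: 6 of 403 (1.49%, exact Clopper-Pearson 95% interval 0.548 to 3.21%) against 622 of 4437 others (14.0%, 13.01 to 15.1%) in the lowest, and 42 of 723 (5.81%, 4.22 to 7.77%) against 1196 of 4114 (29.1%, 27.7 to 30.5%) in the highest. These intervals cover counting error only.

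**Figure D3:**
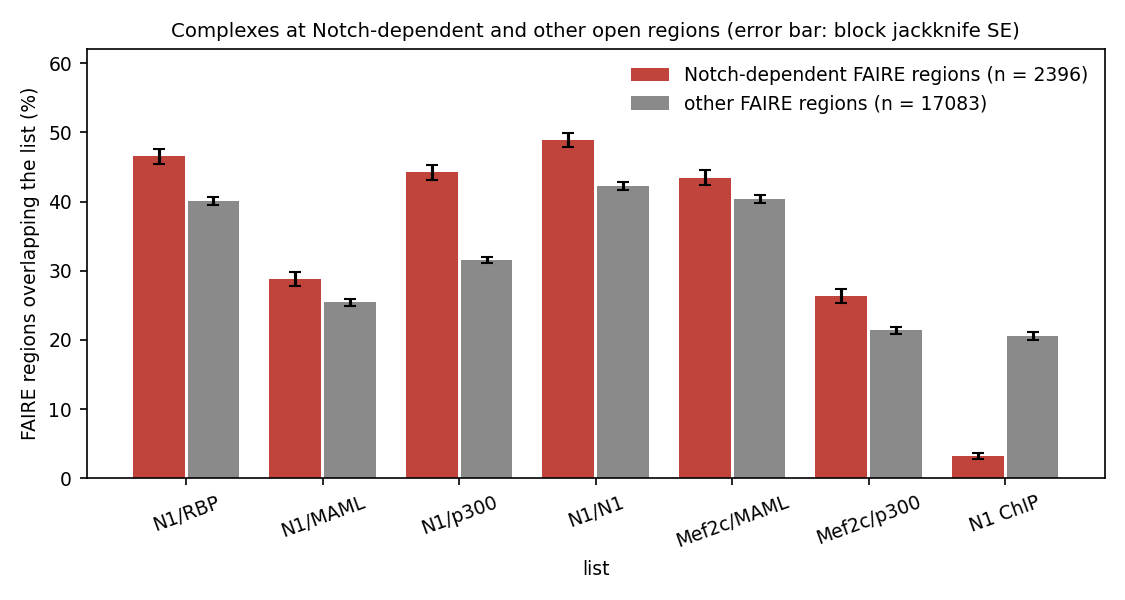
Share of the 2396 Notch-dependent and the 17083 other FAIRE regions that overlap each SpDamID list and N1 ChIP, in percent, with block jackknife SEs. N1/p300 has 44.2% against 31.6%, and N1 ChIP has 3.21% against 20.6%.

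At least 1 N1 complex marked 1549 Notch-dependent regions, 64.6% ± 1.06, against 55.3% ± 0.575 of the others (n = 523 blocks, adjusted p = 1.15e-16). Among Notch-dependent regions, 490 lay in all 4 N1 lists, 504 in N1 lists but no Mef2c list, and 738 in no SpDamID list. The 10 that overlapped all 6 SpDamID lists and ChIP with the highest N1/RBP scores began with chromosome 2, 152566702 to 152568646, at an N1/RBP score of 613 and an N1/MAML score of 740. Next were chromosome 12, 17516781 to 17517366, with an N1/RBP score of 607, chromosome 8, 114267644 to 114271327, with 583, and chromosome 13, 33055345 to 33057304, with 580. N1/RBP scores of the other 6 ran from 514 to 394. The last of them, on chromosome 15 from 13153275 to 13185806, spans 32532 bp.

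ChIP regions were short beside SpDamID regions, with a median of 137 bp against 486 to 754 bp. Of the 22307 ChIP regions, 13812 (61.9%) were under 200 bp and 1 of these lay in any SpDamID list. Of the 5858 of at least 300 bp, 1279 (21.8%) did. In all, 1361 ChIP regions (6.1%) overlapped an SpDamID fragment, each with identical ends. The 5th percentile of length was 302 to 405 bp over the SpDamID lists, so short ChIP regions could hardly be shared with identical ends. Their low share follows from these lengths and is not evidence that the methods disagree. Total FAIRE held 5689 ChIP regions (25.5%), and its share went from 16.5% of ChIP regions under 100 bp to 43.8% of those of 1000 bp or more.

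The highest scoring regions of the lists gathered at a few places that differed with the proteins fused. The 5 highest of N1/p300, with scores of 860 to 870, all lay between 81430389 and 81482435 on chromosome 15, and so did the second and the fifth of Mef2c/p300, at 849 and 831. The other 3 of Mef2c/p300 (867, 837 and 833) lay on chromosome 13 between 83772512 and 83802236, as did 3 of Mef2c/MAML (853, 831 and 789). The remaining pair of Mef2c/MAML lay on chromosome 11, at 50078833 to 50079988 and 50071425 to 50072897, and were the leading pair of N1/MAML, at 869 and 870. All 5 of N1/N1 and the other 3 of N1/MAML lay on chromosome 2 between 26315080 and 26359136. Of N1/RBP, 2 lay there and 3 on chromosome 3 between 97945428 and 97951844. None of these regions on chromosomes 3, 11, 13 and 15 overlapped a FAIRE or ChIP region, whereas all those on chromosome 2 lay in total FAIRE.

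**Figure D4:**
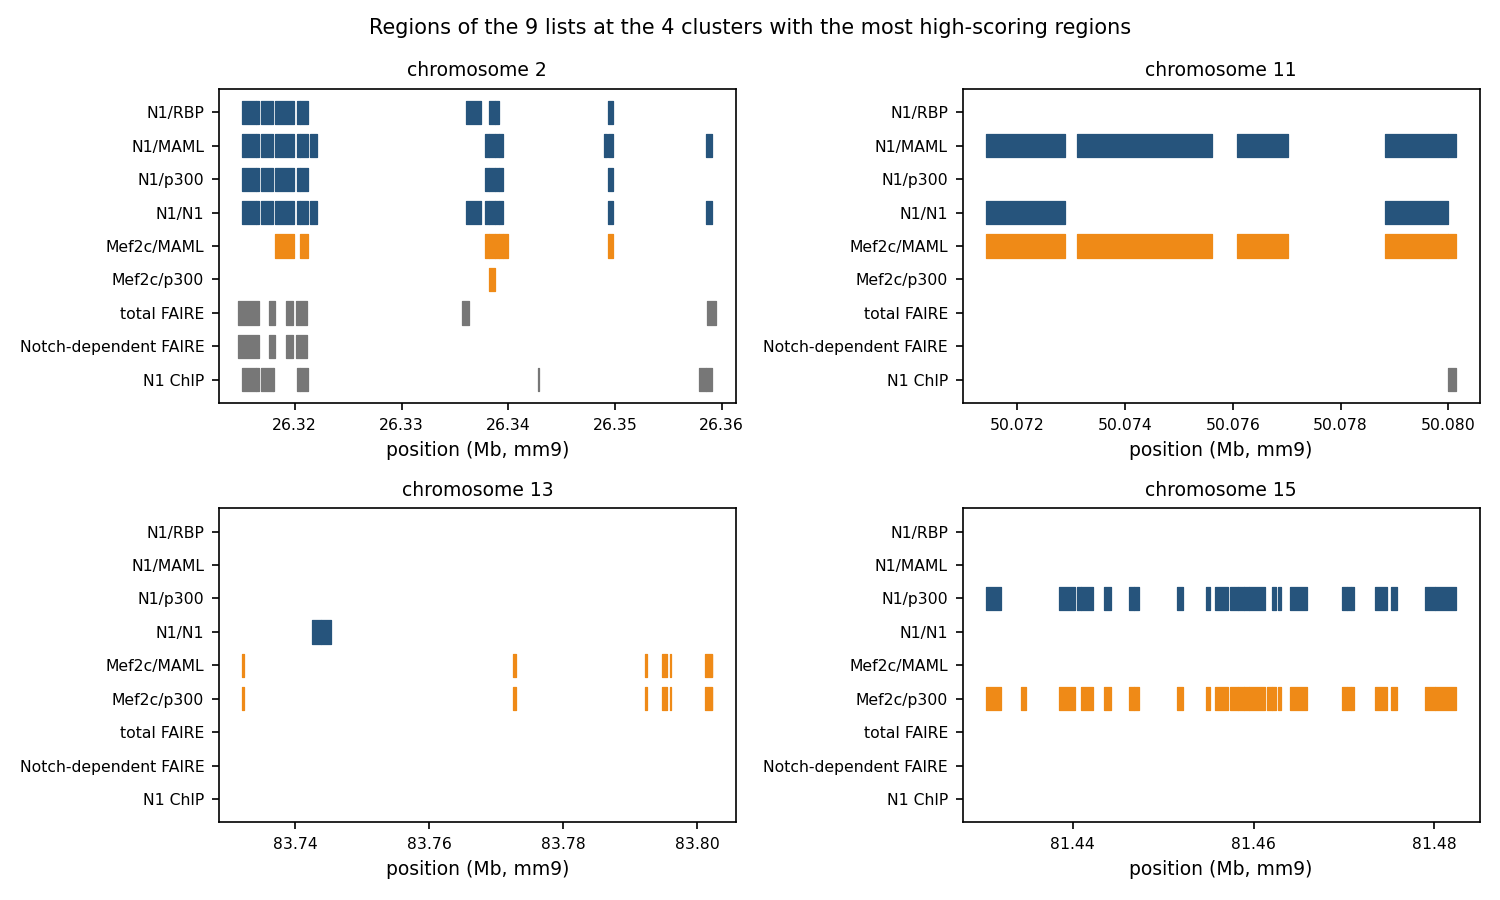
Regions of the 6 SpDamID lists, both FAIRE lists and N1 ChIP (rows) along 4 stretches of mm9 (position in Mb), each bar a region to scale. The chromosome 15 stretch holds 24 N1/p300 and 25 Mef2c/p300 regions and 0 of the other 7 lists, and the chromosome 2 stretch holds regions of all 9 lists.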

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

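Weighted FAIRE regions, the length range, ChIP regions of at least 300 bp and ChIP regions with a measured input were settings chosen after the lists were seen, and the tests with measured input and with the total list's score after the result was seen. The rise is the share of Notch-dependent FAIRE regions in a list minus the share of other FAIRE regions in it, and 5 of 7 differences between rises passed. N1/p300 rose 7.73 points more than Mef2c/p300 and 9.33 points more than N1/MAML. N1/N1 rose 3.32 points more than N1/MAML and -6.01 points relative to N1/p300. On the log2 scale the N1/N1 rise differed from that of N1/MAML by 0.03 (n = 523 blocks, adjusted p = 0.606), so this difference in points goes with the lower level of N1/MAML. N1/RBP rose 23.8 points more than N1 ChIP, whose share fell by 17.4 points.

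The larger rise of N1/p300 than of Mef2c/p300 was set against FAIRE peak strength and length and against the fragment lengths of the lists. With other FAIRE regions weighted to the Notch-dependent ones by length and by score in the total list the difference was 8.58 points (95% interval 6.27 to 10.9), which argues against peak strength and length. Within 405 to 786 bp it was 4.75 points (2.88 to 6.62), so fragment length is not the whole source, though it may carry part. On the log2 scale the difference did not fall. It was 0.215 ± 0.06 in that range and 0.188 ± 0.05 over all lengths. What stays open is a difference between libraries, since Mef2c/p300 has 1. A biological reading, that p300 meets N1 at sites that open with Notch, is a hypothesis that was not tested, and these lists cannot separate it from library differences.

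The smaller share of Notch-dependent than of other FAIRE regions in N1 ChIP was set against 3 technical explanations. Weighting to score in the total list and length left a log2 ratio of -2.56 (95% interval -2.94 to -2.18), ChIP regions of at least 300 bp gave -3.06 (-3.59 to -2.53), and ChIP regions with an input off the fixed value gave -3.72 (-4.76 to -2.68). All 3 stayed below -1, so none of them accounts for the pattern. Still open, and untested, are repeat masking of the ChIP list, the way Notch-dependent peaks were chosen, and ChIP signal that follows open promoters rather than N1; a biological difference in when or where N1 stays bound was not tested either.

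On contigs outside the comparisons there were 43 total FAIRE regions (0.222% of the list) and 7 Notch-dependent FAIRE regions (0.291%), and no control list of FAIRE regions was used here.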

How the results depend on the processing

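No paired analysis was possible because the lists hold no values per library, and no replicate could be left out; depth per library is unknown and limits what can be said of missing regions. Of 707 alternative values for 111 results, 675 kept the direction and the side of the threshold. In 175 of the 707 the observed overlap or difference did not change and only the random placement or the SE could, and of the other 532, 502 kept both. The 675 include all 42 for N1 against Mef2c with the same partner, 54 of 58 for Notch-dependent against other FAIRE, 383 of 388 folds over random placement and 89 of 90 for score quartiles, but 53 of 63 for N1/N1 against the other N1 lists and 48 of 58 for differences of rises, with 7 reversed in each. The length range, single-list, ChIP length, ChIP input and score-and-length weighting alternatives were chosen after seeing the data. In every case below the cause was not tested. Rotation breaks the map of fragments that ChIP regions have in common with SpDamID, so a fold below 1 in ChIP is not evidence of avoidance. Mef2c/p300 regions in N1 ChIP were 0.967-fold at 50% overlap, 0.998-fold merged and 0.954-fold at 405 to 786 bp, none passing, and 1.69-fold with ChIP regions of at least 300 bp and 1.22-fold with measured input. Its score quartiles in ChIP, not passing at first, differed by 0.233 points when merged. At 405 to 786 bp the Notch-dependent differences no longer passed for N1/RBP (1.95 points), N1/MAML (1.29), N1/N1 (1.79) and Mef2c/MAML (1.71). In that range N1/N1 reversed against N1/RBP in total FAIRE (2.94) and Notch-dependent FAIRE (0.26) and against N1/p300 in total FAIRE (2.85). With regions of 1 list only it reversed in total FAIRE against N1/RBP (1.07, not passing), N1/MAML (6.86) and N1/p300 (4.53) and in Notch-dependent FAIRE against N1/MAML (1.02), and gave -0.0621 against N1/RBP. N1/N1 against N1/MAML in Notch-dependent FAIRE did not pass when merged (-0.111) or above the median score (-0.374). Differences of rises that reversed had not passed at first: N1/MAML against Mef2c/MAML gave -1.29 at 50% overlap, -2.68 by region centre, where it passed, -0.425 at 405 to 786 bp and -0.208 weighted to the total list's score and length, and N1/N1 against N1/RBP gave -0.0324 merged, -0.27 above the median score and -0.154 at 405 to 786 bp. N1/N1 against N1/MAML no longer passed above the median score (2.17) or at 405 to 786 bp (0.508), nor N1/N1 against N1/p300 by region centre (-1.95), though on the log2 scale it did (-0.257, n = 523 blocks, adjusted p = 4.78e-07). Pairs with a common protein differed by 0.36 on the log2 scale of the Jaccard index, which did not pass. Regions common to all N1 lists numbered 2668 above the median score, where each list is shorter by construction. Alternatives for gene features, gene lists and motifs were not run.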

Other observations

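All tests of the clusters were chosen after these were seen, and so were the classes of fragments by list. Of 96409 SpDamID fragments, 57982 (60.1%) lay in 1 list and 2904 (3.01%) in all 6. Only 320 fragments lay in all 4 N1 lists and in no Mef2c list. Of these, 12.8% ± 1.99 (SE) lay in Notch-dependent FAIRE, against 9.04% ± 0.485 of the 5410 shared with a Mef2c list, a difference of 3.77 points that did not pass (95% interval -0.0706 to 7.62, n = 480 blocks, adjusted p = 0.0652). In total FAIRE the order was turned, 53.4% ± 2.89 against 60.6% ± 0.998 (n = 480 blocks, adjusted p = 0.0226). The 5480 fragments in both Mef2c lists and no N1 list lay in total FAIRE at 7.26% ± 0.398 and in N1 ChIP at 0.201% ± 0.0622.

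The 50 highest scoring regions of each SpDamID list, 223 distinct regions, formed 8 clusters of at least 3 regions less than 50 kb apart, and 81430389 to 81482435 on chromosome 15 held 20 of the 50 for N1/p300 and 19 for Mef2c/p300. A candidate source is DNA that carries the sequence of a fused protein itself, such as an expression construct, which would give signal where its coding sequence maps. In all 5 clusters with high regions of several lists, those lists had a protein in common: N1 at both 26315080 to 26359136 on chromosome 2 and 13139514 to 13140643 on chromosome 15, MAML on chromosome 11, Mef2c on chromosome 13 and p300 on chromosome 15. As many clusters with a common protein came from 4 of 720 relabellings of the lists (exact permutation p = 0.00556), but the same clusters prompted the hypothesis, so this p cannot count in its favour. Lists with a common protein may also share true binding sites, and the positions of the genes for the fused proteins were not used here. At the 6 clusters that lack high regions of some N1 list, 0 of 42 high regions lay in total FAIRE. By place, 0 of these 6 were open in N1wt cells, against 85 of 166 outside clusters (51.2%, Fisher's exact p = 0.0286). This argues against open chromatin of N1wt cells as their source. The clusters on chromosomes 11 and 13 and from 81430389 on chromosome 15 also hold high regions of Mef2c lists. Open chromatin in cells with the Mef2c fusions is unknown, so for those regions it is not excluded. For the 2 clusters with high regions of all 4 N1 lists, open chromatin as a source stays open. Both had high regions in total FAIRE (Fisher's exact p = 0.498), and 2 places are few. All 3 high regions of the one on chromosome 15 lay in 1 FAIRE region, 13129703 to 13153225. The FAIRE lists are from N1wt cells and ChIP used tagged N1, so DNA that carries the N1 sequence could give FAIRE and ChIP signal too. Overlap with FAIRE or ChIP therefore cannot separate open chromatin from such DNA at these 2 clusters. The 2 differ, however: the one on chromosome 2 held 10 N1 ChIP regions and the one on chromosome 15 held 0. Mef2c/MAML, which holds no N1, had 8 regions in the first and 3 in the second, where its scores were 533, 601 and 637. N1 sequence would not give that Mef2c/MAML signal, but ChIP and Mef2c/MAML have 1 library each, so the source stays open.

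The Notch-dependent share of total FAIRE regions differed between chromosomes, from 6.03% of 365 on the X chromosome (exact 95% interval 3.82 to 8.98%) and 7.84% on chromosome 4 to 15.9% of 1341 on chromosome 1 (14.0 to 17.95%). A chi-square of 129 was reached by 5 of 10000 exchanges of 5 Mb blocks between chromosomes (p = 0.00060), which argues against chance clustering. The median FAIRE score per chromosome gave a Spearman rho of 0.265 (permutation p = 0.261) and a Pearson r of 0.393 (permutation p = 0.0861) over 20 chromosomes. Without chromosomes 14 and 19 the Pearson r was 0.249 (permutation p = 0.316), so a part played by peak strength stays open. No biological explanation was tested.

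Among the 100 ChIP regions with the highest deposited ratio, 58 had an input off the fixed value, against 9.88% of all ChIP regions. Inputs below 0.1 were found in 1043 ChIP regions, with a median ratio of 22.9, against 14.7 for inputs at the fixed value. The ratio divides by the input, so a lower input raises it by construction. Median ChIP signal was 1.36 in those regions and 1.47 at the fixed value.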
